A study of Mus musculus with 4 samples.

How the data were processed

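Whole-genome bisulfite sequencing libraries of 2 Control and 2 Gadd45a, Gadd45b and Gadd45g triple-knockout (TKO) clones of E14tg2a mouse ES cells were analysed from per-cytosine methylation calls. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, DNA was purified with a column kit with added RNase, libraries were prepared with a PCR-free kit, and bisulfite conversion used a commercial kit. Trim Galore 0.4.4, Bismark 0.18.0, methylKit 1.3.3 and the mouse build mm10 are named in the submitters' processing notes. Which settings were used, whether duplicate reads were removed and which role methylKit had are not given in the sources used here. The deposited values are counts: for each of 43735674 cytosines of CpGs, on each strand, the authors gave the number of methylated and of unmethylated calls in 1 library, unpooled and without normalization. Between 8.14% and 8.82% of the listed cytosines had no calls. Which count was the methylated one was settled from the values, since it was near 0 on the mitochondrial chromosome. If duplicate reads remain, or the overlap of read pairs was counted more than once, calls are less independent than their number implies, which is the reason for the overdispersion term below.

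Both strands of each CpG were joined, giving 21867837 CpGs on 22 chromosomes. Total calls were 564406428, 684175815, 649122875 and 633056465 in Control 1, Control 2, TKO 1 and TKO 2, with a median of 22, 27, 26 and 27 calls per autosomal CpG, and 92.1% to 92.9% of CpGs had at least 5 calls. A level is the percentage of methylated calls among all calls of a region. The mean ± SD of a group is over its library levels (n = 2), while differences of tiles and gene ends are between the levels over the pooled calls of each group, as the model fits them. Analyses used chromosomes 1 to 19 and X. Median calls per CpG in Control 1 rose with CpG density from 15.5 to 35.6, whereas in Control 2 they lay between 24.5 and 29.4.

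The regions were tiles of 1000 bp with at least 3 CpGs and 20 calls in every library, gene ends with the same minimum, and single CpGs with at least 5 calls in every library. Each was tested with a quasi-binomial logistic model on methylated and unmethylated counts with group as the only term. Overdispersion was moderated across regions with squeezeVar of limma 3.58.1 in R 4.3.3, with a floor of 1, followed by an F test and Benjamini-Hochberg adjustment. A region was called at an adjusted p under 0.05 with a difference of at least 20 points for tiles and CpGs and 10 points for gene ends. For tiles and gene ends the moderation put all weight on the common value in the results as reported. It was fitted anew in each other setting that used it. The test was checked on simulated calls at 32509 gene ends and 400000 tiles with 200 changed regions and an overdispersion of 3. The values fitted to the data were higher, at 17.4 for gene ends and 9.20 for tiles, and changes were placed only at intermediate mean levels. Rates of recovery therefore describe the simulated setting and not the power in these data. With no difference between libraries the test recovered 93% of changes of 30 points and 99.5% of changes of 50 points at gene ends, and 64% and 96% at tiles. A comparison of single values over the 4 libraries used a two-sided exact permutation test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 served for counting and exact intervals at a confidence level of 95%, and edgeR 4.0.16 for an alternative test.

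Promoters had been planned from the 5' end of genes, but the gene table used (GRCm38.p6, the assembly that mm10 names) gave no strand and no exons. In their place the CpG-richer end of each protein-coding or lncRNA gene was used, 1000 bp outside and 500 bp inside the gene, chosen on the number of CpGs only, with ties left out. These gene ends held a median of 31 CpGs against 13 at the other end, and at 76.5% of genes with both ends tested the chosen end was the less methylated one. For some genes it is not the promoter. Exons and introns were not analysed here, and Gadd45 coverage was taken over the whole gene. Gene names and spans came from the same table.

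Lists of imprinted, pluripotency, germline, 2C-like, DNA methylation machinery, developmental regulator and reported GADD45 target genes, and of primitive endoderm, trophoblast, primed epiblast, fibroblast and neural markers, were fixed before the data were examined, as were the tests, the thresholds and most of the other settings tried. Of their symbols 28 stood in more than 1 list. Lists were tested with camera of limma on log2((methylated + 1)/(unmethylated + 1)) at a preset correlation of 0.01, adjusted over the 12 lists, and again with an estimated correlation. Genes were named by a fixed rule: the 3 Gadd45 genes; the 12 gene ends with the largest rise and the 12 with the largest fall among those called with both TKO clones on the same side of both Control clones, without predicted genes and small RNAs; up to 4 called members of each list, or else its 2 largest differences as values; and the 5 longest runs of called tiles at most 1000 bp apart. No fall met this rule. The labels do not say whether the clones were sequenced in 1 batch, and p-values reflect only the spread between these clones, pooled over regions.

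Coverage was compared in bins of 250000 bp as calls per CpG divided by the autosomal median at the same CpG density in the same library, and stretches of at least 4 bins under 0.7 times the 2 best-covered libraries were listed. Alternatives were each library left out in turn, the replicate number as a block, no overdispersion, edgeR, other coverage minimums, tile sizes, gene-end windows and minimum differences, centred levels, thinned calls and the removal of tiles with very high coverage. The use of the CpG-poorer gene end, the counting of overlapping gene ends once and coverage matched on CpG density were chosen after seeing the data.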

Results

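Genomic DNA of 4 clones of E14tg2a, a male mouse embryonic stem (ES) cell line, was examined by whole-genome bisulfite sequencing, in which unmethylated cytosines are read as thymine and methylated cytosines stay cytosine. Both TKO clones had been edited with CRISPR/Cas9 to knock out Gadd45a, Gadd45b and Gadd45g together, and both Control clones had passed through the same editing system without a specific guide RNA. The cells were grown on gelatin in medium with serum and LIF, a cytokine that keeps mouse ES cells undifferentiated. The 3 GADD45 proteins are stress-induced adaptors with reported roles in DNA repair and in the removal of DNA methylation, so the comparison asks where the methylome differs without them. Each group had n = 2 clones, named here Control 1, Control 2, TKO 1 and TKO 2 after the replicate numbers of the labels. The libraries held 564406428, 684175815, 649122875 and 633056465 methylation calls at CpGs in that order. The median autosomal CpG, with both strands joined, carried 22, 27, 26 and 27 calls.

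Coverage of the Gadd45 loci differed between the groups. In both TKO clones a stretch of CpGs inside each of the 3 genes had almost no calls, while both Control clones were covered throughout. In Gadd45a (mm10 chromosome 6, 67035096 to 67037407) the stretch spanned 67036960 to 67037103 and held 16 of the gene's 110 CpGs, with a mean of 27.1 and 28.6 calls per CpG in Control 1 and Control 2 against 0.188 and 0.25 in TKO 1 and TKO 2. In Gadd45b (chromosome 10, 80930091 to 80932204) it spanned 80930204 to 80930532 and held 25 CpGs, with 53.2 and 28.0 calls in the Control clones against 0.08 and 0.04 in the TKO clones. In Gadd45g (chromosome 13, 51846675 to 51848475) it spanned 51846741 to 51847473 and held 42 CpGs, with 48.0 and 29.6 against 0.0952 and 0.0238 calls. No CpG of these stretches had more than 2 calls in a TKO clone. The stretches are those common to both clones, and the longest run of CpGs with at most 2 calls held 17 CpGs in TKO 1 and 36 in TKO 2 at Gadd45a, 26 and 27 at Gadd45b and 42 and 43 at Gadd45g. Whether the stretches are exonic was not analysed here, because the gene table used carried no exons. Outside the common stretch, TKO 1 covered Gadd45a and Gadd45b at 50.6% and 40.8% of its library mean per CpG, while TKO 2 covered them at 87.6% and 92.5%. Control 1 covered the rest of the 3 genes at 155% to 162% of its mean, and this library also had more calls per CpG in CpG-dense DNA genome-wide.

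**Figure D1:**
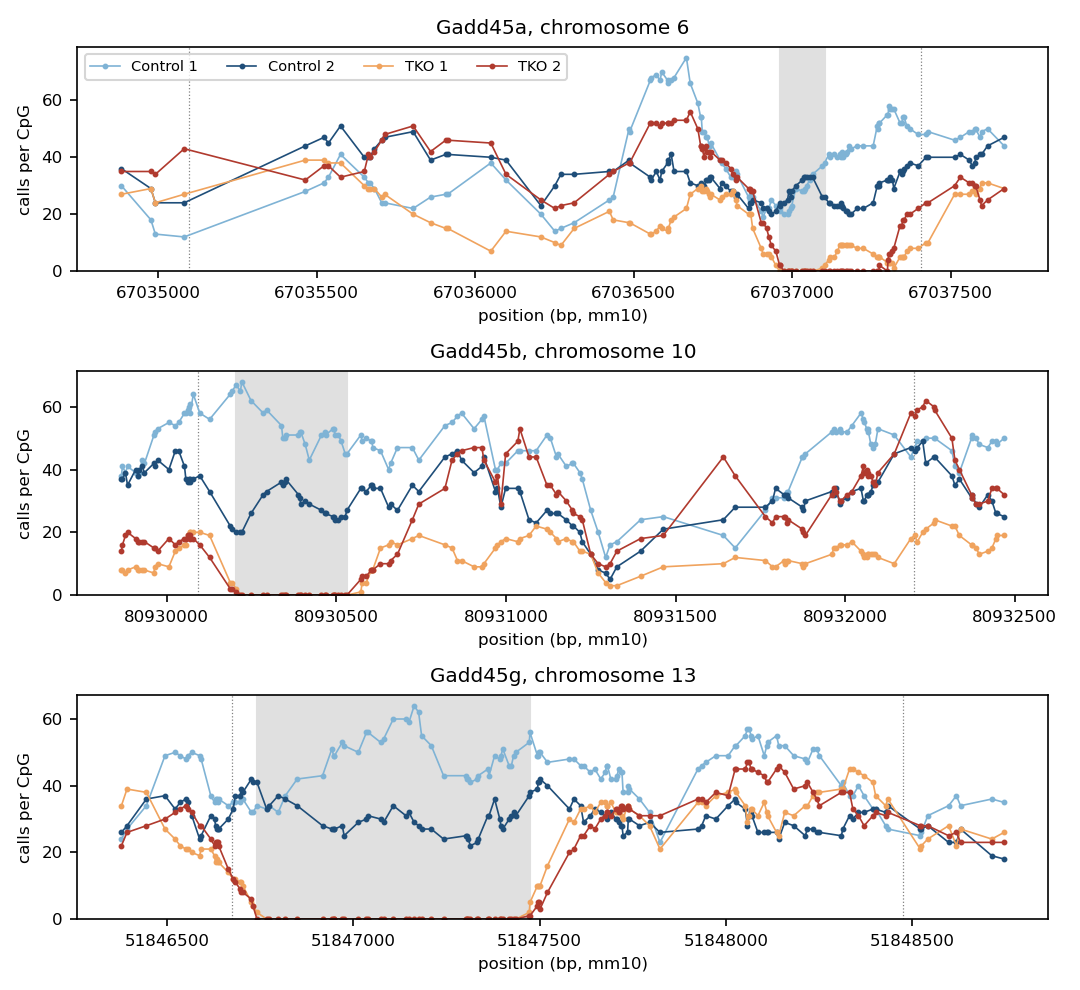
Number of calls per CpG (vertical axis) against position in bp (mm10, horizontal axis) over Gadd45a, Gadd45b and Gadd45g in the 4 libraries, with dotted lines at the gene ends and grey bands over the stretches without calls in both TKO clones. In the grey bands, of 16, 25 and 42 CpGs, no CpG had more than 2 calls in a TKO clone.

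Genome-wide CpG methylation was 56.7% in Control 1, 72.9% in Control 2, 75.6% in TKO 1 and 75.5% in TKO 2, counted over chromosomes 1 to 19 and X. The group means were 64.8% ± 11.5 (SD, n = 2) for Control and 75.6% ± 0.0401 (SD, n = 2) for TKO, a difference of 10.8 percentage points with both TKO clones above both Control clones. This difference was smaller than the SD of the Control clones, and Control 2 alone lay 2.64 points under the TKO mean. The two-sided exact permutation test over the 6 groupings gave p = 0.333, the smallest value that 2 clones against 2 can reach, so this comparison could not pass 0.05. On the X chromosome, present as 1 copy in male cells, the levels were 57.7%, 75.3%, 78.2% and 79.0% in the same order. Methylated calls on the mitochondrial chromosome, taken as an upper limit of unconverted cytosines, made up 0.134% in Control 1 (95% exact interval 0.124 to 0.145), 0.125% in Control 2 (0.119 to 0.1302), 0.0744% in TKO 1 (0.0701 to 0.0789) and 0.0641% in TKO 2 (0.0590 to 0.0694). Intervals of this kind cover counting error only.

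**Figure D2:**
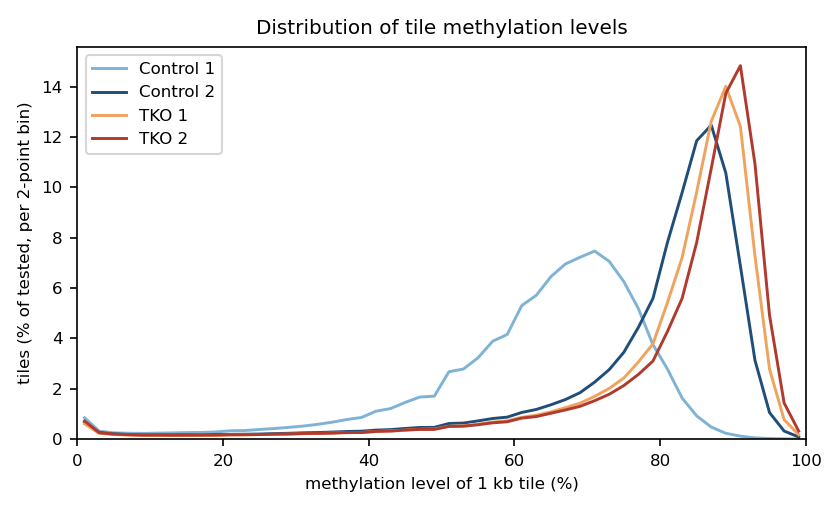
Share of the tested 1 kb tiles (vertical axis, percent per 2-point bin) against their methylation level (horizontal axis, percent) in each of the 4 libraries. The curve of Control 1 is shifted to lower levels, with a median of 66.0%, while the medians of Control 2, TKO 1 and TKO 2 were 83.3%, 86.0% and 87.3%.

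Across the genome in 1 kb tiles, the tiles called were higher in the TKO clones, and 4 of the 5 longest runs of them lay over imprinted genes, of which only 1 parental copy is expressed. Of 2128449 tiles tested, 2599 passed the test with a level at least 20 points higher in TKO and none passed with a lower level, and both TKO clones lay above both Control clones in 2509 of the 2599. The median difference over all tiles was 9.57 points. Both TKO clones were above both Control clones in 59.6% of all tiles and below both in 0.357%, where exchangeable libraries would give 16.7% each way. All tiles share the genome-wide order of the libraries, so these shares restate that order. Of the 2599 called tiles, 178 had both TKO clones at least 20 points above both Control clones and 1231 at least 10 points, and over all tiles, called or not, a margin of 20 points was met by 2336 upwards and 8 downwards.

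The tile calls came from a quasi-binomial model with limma moderation and Benjamini-Hochberg adjustment at 0.05. At an unadjusted p under 0.05, 246836 tiles were higher and 55 lower, and the binomial model without overdispersion called 64323 higher and 78 lower. The moderation gave all tiles 1 common overdispersion of 9.20, so the spread between clones at a single tile did not enter its p-value. Leaving out 1 library changed the count to 1050 higher and 38 lower without Control 1 (274 of the higher tiles shared with the full comparison), to 840581 and 113 without Control 2, to 69 and 0 without TKO 1 and to 83 and 0 without TKO 2. With each library's levels centred to the same mean and the overdispersion fitted anew, 27 tiles were higher and 2 lower. Simulated data had the library differences seen here, 100 tiles changed each way and an overdispersion of 3, under the 9.20 fitted here. The test recovered 38 rises and no falls of 30 points, and 75 rises and 29 falls of 50 points. A fall thus had less chance there of being called than a rise. The test also called 45 and 44 unchanged tiles, more than the rises of 30 points it recovered.

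CpG-island-like sequence, mostly unmethylated in ES cells, differed least in points between the group means among the density classes. In proportion it was not spared: Control 1 was at 81.2% of the level of Control 2 there and at 79.2% to 82.4% in the other density classes. Tiles with fewer than 10 CpGs per kb had a mean level of 71.8% ± 11.8 in Control and 83.2% ± 0.793 in TKO (SD, n = 2), a difference of 11.4 points. The difference was 10.1 points for tiles with 10 to 19 CpGs, 9.02 points for 20 to 39 CpGs and 2.04 points for 40 or more CpGs, where Control was at 11.5% ± 1.68 and TKO at 13.5% ± 0.534. By mean level over all libraries, the difference was 0.837 points in tiles under 10%, 7.34 points between 10% and 50%, 12.6 points between 50% and 80% and 10.2 points at 80% or more. Tiles over CpG-richer gene ends differed by 8.13 points, gene bodies outside them by 10.7 points and tiles outside genes by 11.1 points. In all these classes both TKO clones were above Control 1, the classes were not tested against clone spread, and without Control 1 the differences were between 0.314 and 3.61 points, with 3.06, 3.22 and 3.37 points in the 3 classes under 40 CpGs, the reverse of the order with all libraries. The class of 20 to 39 CpGs held 1668 of the 2599 called tiles, 1.58% of its tiles, with an odds ratio of 34.95 by Fisher's exact test (95% interval 32.2 to 37.9). These odds describe the calls only, since neighbouring tiles are not independent and tiles with more CpGs carry more calls.

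The called tiles formed 2315 runs, 2109 of them single tiles and 37 of at least 3 tiles. The longest run, of 9 tiles at chromosome 6, 30732001 to 30743000, lay over Mest, a paternally expressed imprinted gene, and had levels of 19.3% in Control 1, 90.2% in Control 2, 91.5% in TKO 1 and 91.5% in TKO 2, so it separated Control 1 from the other 3 libraries and no tile of it was called without Control 1. The other run of 9 tiles, at chromosome 2, 174291001 to 174301000, lay in Gnas, an imprinted locus coding for a G protein subunit, with levels of 8.46% and 8.68% in the Control clones and 46.9% and 43.1% in the TKO clones. A run of 8 tiles at chromosome 1, 63196001 to 63205000, overlapped Gpr1 and Zdbf2, with 17.8% and 17.4% in Control against 56.8% and 88.7% in TKO. The 8 tiles at chromosome 5, 143125001 to 143136000, overlapped the predicted gene Gm38734, with 38.5% and 52.0% in Control against 76.9% and 71.2% in TKO. A run of 7 tiles at chromosome 2, 157557001 to 157564000, lay over Blcap and the imprinted gene Nnat inside it, with 31.3% and 43.0% in Control against 64.1% and 93.7% in TKO. Without Control 1, all 9 tiles were still called in the Gnas run, all 8 in the Gpr1 and Zdbf2 run, 5 of 8 in the Gm38734 run and 5 of 7 in the Blcap and Nnat run.

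Most of the largest called differences at gene ends lay at imprinted genes, with higher levels in the TKO clones. The imprinted list as a whole had an adjusted p = 0.863 with an estimated correlation (camera, limma), and at Peg13, Mest, H19 and Meg3 the difference was -0.341, -2.01, 4.88 and 5.20 points without Control 1. For each gene the CpG-richer of its ends was taken, as a stand-in for the promoter, and of 32509 such gene ends 61 passed the test with a rise of at least 10 points in TKO and 1 passed with a fall. Rise and fall here give the level in TKO against Control and do not say which group changed. The largest rise was at the shared end of Plagl1, a paternally expressed zinc-finger gene, and its non-coding partner Hymai (chromosome 10, 13089832 to 13091332 for Plagl1), from 22.2% ± 20.8 in Control to 92.3% ± 2.25 in TKO (SD, n = 2; adjusted p = 2.52e-57, limma moderation). Nap1l5 (chromosome 6, 58906626 to 58908126) rose from 26.01% ± 23.2 to 93.6% ± 1.31 (adjusted p = 2.69e-35, limma moderation). Control 1 and Control 2 lay apart at both, at 7.51% and 36.9% for Plagl1 and 9.58% and 42.4% for Nap1l5. This spread at the single gene did not enter these p-values, which rest on an overdispersion common to all gene ends. Zdbf2 (chromosome 1, 63199358 to 63200858) rose from 1.98% ± 2.11 to 66.8% ± 38.99, with 39.2% in TKO 1 and 94.4% in TKO 2, and Nnat (chromosome 2, 157559078 to 157560578) from 7.91% ± 2.03 to 67.4% ± 36.6, with 41.6% in TKO 1 and 93.3% in TKO 2.

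Several imprinted gene ends were almost unmethylated in both Control clones and at intermediate levels in both TKO clones. Mcts2 (chromosome 2, 152686148 to 152687648), a retrogene inside H13, rose from 4.92% ± 2.65 to 43.8% ± 4.46, and Zrsr1 (chromosome 11, 22971005 to 22972505), inside Commd1, from 3.77% ± 0.841 to 41.4% ± 13.6. Peg3 and Usp29, neighbours with overlapping ends on chromosome 7 (6729962 to 6731462 and 6729559 to 6731059), rose from 4.88% ± 1.65 to 40.5% ± 0.133 and from 2.65% ± 3.11 to 40.1% ± 5.68. Zim3 (chromosome 7, 6976162 to 6977662), in the same cluster, rose from 31.8% ± 14.5 to 72.4% ± 1.75. H19 (chromosome 7, 142577646 to 142579146), a maternally expressed non-coding RNA, was called higher on 33.9% in Control 1 against 88.2% in Control 2, 93.7% in TKO 1 and 92.6% in TKO 2. Apart from Hymai, which was not in the imprinted list but shares the Plagl1 window, the only gene outside that list among the 12 named rises, the largest with both TKO clones above both Control clones and predicted genes left out, was Stag1, a cohesin subunit (chromosome 9, 100596709 to 100598209), at 29.6% and 60.4% in Control and 77.0% and 78.3% in TKO. The single gene end that fell, named after its values were seen, belonged to the predicted non-coding gene Gm51701 on chromosome 9, at 35.7% and 42.7% in Control and 25.5% and 23.6% in TKO.

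Both TKO clones lay above both Control clones at 52 of the 61 gene ends, and the calls again rested on 1 common overdispersion, here 17.4, so clone spread at a single gene did not enter its p-value. The count of rises was 20 without Control 1 (13 shared), 16103 without Control 2, 18 without TKO 1 and 17 without TKO 2, and that of falls 1, 2, 1 and 0. edgeR called 12 rises and no fall, and the binomial model 9097 rises and 3 falls. With levels centred 3 rises were left, at Mcts2, Peg10 and Sgce (centred adjusted p 0.0117, 0.0151 and 0.0106, limma moderation), and the other 11 of the 12 rises named by the fixed rule lost their call with centred differences of 19.6 to 67.0 points. The overdispersion was fitted anew there, and p did not follow the size of the difference. Plagl1 kept 67.0 points at an adjusted p = 0.122 (limma moderation), against 22.3 points at Sgce. Clone spread at a single gene can enter p-values of a refitted setting, and a lost call there is not a lost difference. Without Control 1, Zdbf2 and Nnat lost their call with differences still at 64.6 and 62.0 points, Stag1 at 17.4 points and H19 at 4.88 points. Without TKO 1 or TKO 2, Zim3 was not called at 43.0 and 40.5 points nor Stag1 at 34.99 and 33.6 points, and H19 was not called without TKO 2 at 36.97 points. Simulated gene ends had the observed library differences and an overdispersion of 3, under the 17.4 fitted here. The test recovered 88 of 100 rises and 6 of 100 falls of 30 points, and 95 rises and 78 falls of 50 points. It also called 10 and 26 unchanged gene ends.

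Of the imprinted list, 61 gene ends were tested, 15 rose, none fell and the remainder did not pass the test, and 18 rose when adjusted over the list alone. Camera placed the list above other gene ends (adjusted p = 1.89e-24, limma). With an estimated correlation of 0.484 the list had an unadjusted p = 0.137 and the adjusted p = 0.863 shared by all lists (camera). The median difference of its members was 6.64 points and the mean 15.2 points. The 15 included 5 genes named after their values were seen. Peg10 and Sgce, which share a promoter region on chromosome 6, rose from 2.62% ± 0.402 to 34.8% ± 2.73 and from 1.17% ± 0.0792 to 31.9% ± 0.954. Peg13 stood at 23.7% in Control 1 but at 95.2%, 93.9% and 95.9% in Control 2, TKO 1 and TKO 2, Mest at 19.8% against 87.1%, 88.0% and 82.4%, and Meg3 at 12.7% against 37.2%, 39.8% and 44.99%. Both TKO clones exceeded both Control clones at 13 of the 15, and both Control clones were under 10% at 8 of them. With the overlapping ends of Peg3 and Usp29 and of Peg10 and Sgce joined, the 15 were 13 loci and the 8 were 6. Against Control 2 alone, where the spread comes from the TKO clones only and Control 2 is assumed to vary like them, 11 of the 15 differed by at least 10 points and 9 of those, or 7 loci, were called, while Peg13, H19, Mest and Meg3 differed by under 10 points.

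**Figure D3:**
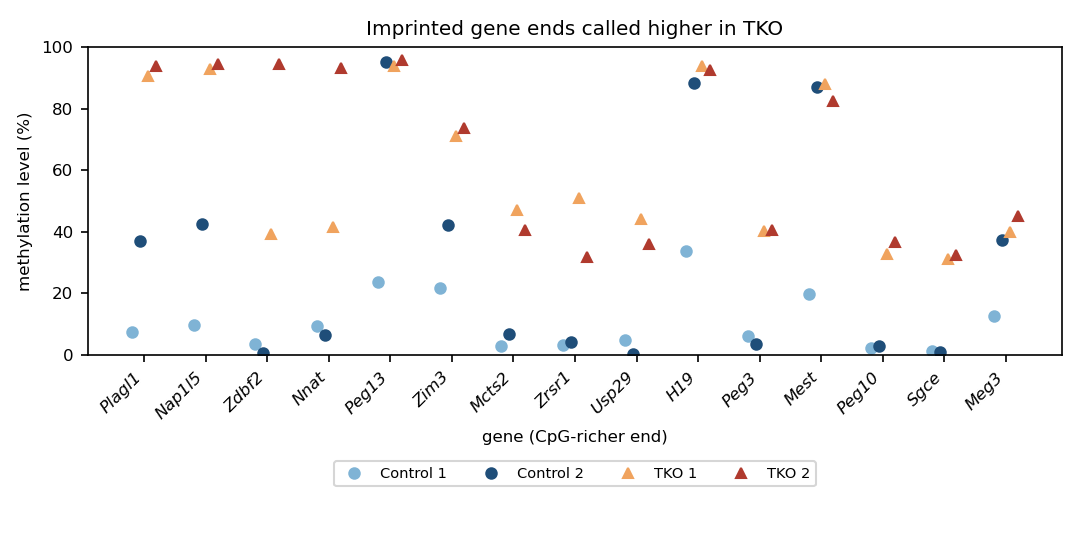
Methylation level in percent (vertical axis) at the CpG-richer end of the 15 imprinted genes called higher in TKO (horizontal axis), 1 point per library, circles for Control and triangles for TKO. At 8 genes both Control clones were under 10%, and at Peg13, H19 and Mest Control 2 lay with the TKO clones.

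None of the other 11 lists had a member called over all gene ends tested. Camera placed the lists of pluripotency genes (adjusted p = 1.84e-06), developmental regulators (3.10e-15), primed epiblast markers (0.000107) and neural markers (0.00123) below other gene ends (limma). With an estimated correlation these lists had unadjusted p of 0.203, 0.303, 0.256 and 0.429 and the adjusted p = 0.863 shared by all lists (camera). Their median differences were nevertheless above 0, at 0.458, 0.517, 0.965 and 1.24 points, as were their means of 3.23, 1.73, 2.69 and 2.68 points. Camera compares a list with the other gene ends, and does so on log2 ratios and not on points. Over all gene ends the median difference was 6.13 points. In Control 2 the mean levels of these lists were 13.3% to 21.6%, against 43.4% over all gene ends, and camera did not match on level. Without Control 1 the pluripotency list was no longer called (adjusted p = 0.147, limma) and the germline list was called above other gene ends (adjusted p = 0.00356), both at the preset correlation, while with all libraries the germline list had adjusted p = 0.863 with an estimated correlation. Developmental regulators stayed low in all 4 libraries, with mean levels of 8.37%, 13.3%, 13.2% and 11.6% in Control 1, Control 2, TKO 1 and TKO 2.

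Dnmt3l, Duxf3 and 7 germline genes were the members of these lists that rose when each list was tested by itself. Of 38 pluripotency genes tested, 1 rose when adjusted over the list alone, Dnmt3l, the cofactor of the de novo methyltransferases, at 47.8% ± 17.2 in Control and 70.7% ± 3.91 in TKO, and Lifr, the LIF receptor, stood at 59.4% ± 21.6 and 79.4% ± 0.298. Of 42 genes of the DNA methylation machinery, Dnmt3l again was the 1 called when adjusted over the list alone. Dppa3 stood at 60.6% ± 22.6 and 74.5% ± 7.69, with 1 Control clone above the TKO mean. Of 34 genes of the 2C-like state, a rare state resembling the early embryo, 1 rose when adjusted over the list alone, Duxf3 (72.8% ± 12.02 and 88.0% ± 1.18), and Tdpoz1 stood at 52.5% ± 0.607 and 68.5% ± 5.02. Of 65 germline genes 7 rose when adjusted over the list alone, and the largest differences, which did not pass, were at Xlr3a (60.7% ± 28.5 and 86.5% ± 6.03) and Xlr4a (65.9% ± 28.3 and 88.7% ± 1.54). The Control clones lay far apart at Dnmt3l, Lifr, Dppa3, Duxf3, Xlr3a and Xlr4a, as their Control SDs show. The differences at these genes therefore rest largely on 1 Control clone, unlike at Tdpoz1 with its Control SD of 0.607. Duxf3 and the Xlr genes belong to families of near-identical copies, among which reads can be misplaced, so their values are uncertain.

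None of the 124 developmental regulators, 21 reported GADD45 targets, 19 primitive endoderm, 18 trophoblast, 17 primed epiblast, 20 fibroblast or 18 neural marker genes passed when adjusted over the list alone. Their largest differences were at Gata5 (15.6 points) and Pax8 (10.6) among developmental regulators, Bglap (13.9) and Mmp9 (13.8) among GADD45 targets, Cubn (15.9) and Hnf4a (13.3) among primitive endoderm markers and Prl3d1 (21.3) and Rhox6 (17.6) among trophoblast markers. In the remaining lists they were at Cer1 (13.7) and Wnt8a (11.1) for primed epiblast, Col6a1 (13.8) and Col1a1 (13.6) for fibroblast and Dcx (13.8) and Rbfox3 (10.6) for neural genes. Camera did not call the lists of 2C-like genes (adjusted p = 0.343, limma), germline genes (0.176), DNA methylation machinery (0.343), GADD45 targets (0.372), primitive endoderm (0.159), trophoblast (0.467) or fibroblast markers (0.388).

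The ends of the knocked-out genes themselves carried little methylation except Gadd45b in TKO 1. Gadd45a stood at 2.39% and 6.56% in Control and 9.16% and 9.97% in TKO, and Gadd45g at 0.259% and 0.688% in Control and 0% and 0.370% in TKO, and neither passed the test. Gadd45b was called higher, but on TKO 1 alone, with 0.213% and 0.749% in Control, 22.1% in TKO 1 and 0.504% in TKO 2. Without TKO 1 its difference was 0.0787 points. These windows include part of the stretches without calls, so TKO values come from the CpGs beside them.

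At single CpGs no difference passed the test. Of 19327820 CpGs with at least 5 calls in every library, the quasi-binomial test with limma moderation called none in either direction, with 382485 higher and 1005 lower at an unadjusted p under 0.05. Fisher's exact test on calls pooled by group, which ignores the spread between clones, called 760922 higher and 757 lower. The median tested CpG had 23, 28, 27 and 28 calls in Control 1, Control 2, TKO 1 and TKO 2, and which size of difference the test could detect at a single CpG was not measured.

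Coverage along the chromosomes differed between clones on chromosome 14. After matching on CpG density, Control 2 had 0.496 times the coverage of the 2 best-covered libraries of each bin from 63000001 to 98000000, and TKO 1 had 0.504 times that coverage from 63000001 to 90750000. By the same measure Control 2 was at 0.520 from 41250001 to 45250000 and TKO 1 at 0.517 from 43500001 to 45250000. From 45.5 to 63 Mb low coverage was common to all 4 libraries, at 0.481 to 0.492 of the autosomal median from 45500001 to 55500000 and at 0.548 to 0.563 from 55500001 to 63000000. At the bin starting at 63000001 Control 1 and TKO 2 changed from 0.558 and 0.557 to 1.11 and 1.07, while Control 2 and TKO 1 stayed at 0.538 and 0.536. The X chromosome was at 0.467 in Control 1, 0.481 in Control 2, 0.487 in TKO 1 and 0.477 in TKO 2. Control 2 further had 0.506 times the coverage of the 2 best-covered libraries at chromosome 10, 53000001 to 55000000. Of the shares of calls per chromosome and library, 6 departed from the other 3 libraries by over 10%, and this count was 2 without tiles of very high coverage, which made up 0.147% of tiles and 14.2% to 19.7% of calls.

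**Figure D4:**
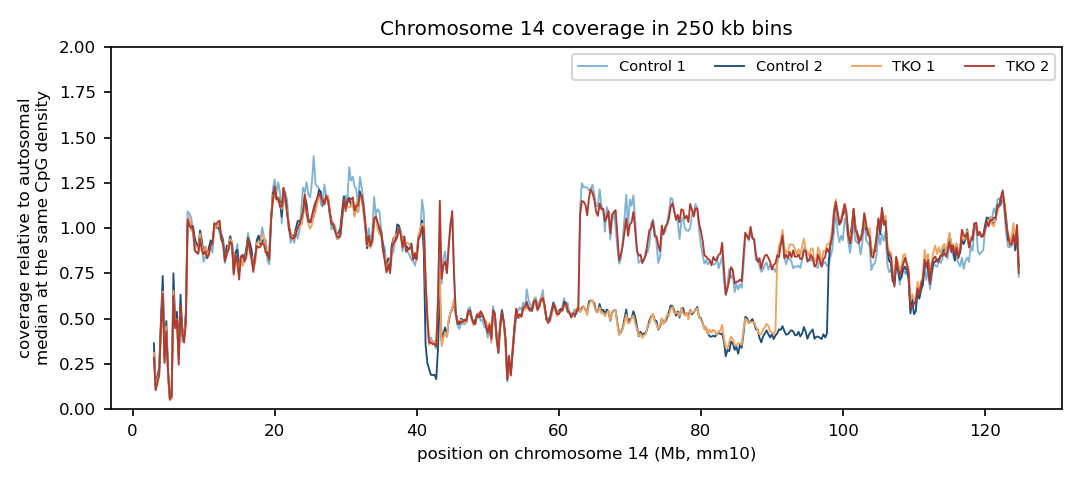
Coverage in bins of 250000 bp relative to the autosomal median at the same CpG density (vertical axis, ratio) along chromosome 14 (horizontal axis, Mb, mm10), 1 line per library. Between 63 and about 90 Mb the lines of Control 2 and TKO 1 lie at about 0.5 times those of Control 1 and TKO 2, and all 4 are low from 45.5 Mb to 63 Mb.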

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

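The tests of conversion and of the coverage tilt were chosen only after the result was seen; both tests of a common factor were fixed before their values were computed. Chromosome Y, which no comparison used, showed the same order of the libraries as the rest of the genome: its mean level in TKO was 78.85%, with 79.1% in TKO 1 and 78.6% in TKO 2 (n = 2), above 59.6% in Control 1 and 77.0% in Control 2. It stands here as a signal above the Control level on a chromosome left out of the comparisons, and its gap is again mostly that of Control 1. The values come from the same 4 libraries, so they are no independent support. The 514458 CpGs of this chromosome carried 801546 to 1135065 calls per library, far fewer per CpG than the autosomes.

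Control 1 lay far under the other 3 libraries genome-wide, at 56.7% against 72.9% to 75.6%. More complete conversion of unmethylated cytosines in Control 1 is argued against by its mitochondrial share of methylated calls, which at 0.134% was the highest of the 4, and its coverage tilt to CpG-dense DNA by its level staying at or under 82.4% of that of Control 2 in each density class. A single factor for all regions would leave Control 1 as tightly tied to Control 2 as the TKO clones are. Unmethylated DNA in the sample or conversion of methylated cytosines would give such a factor if even along the genome. The spread of Control 1 about such a factor was 2.05 times the larger TKO spread over 1 kb tiles, where calls of 1 read are not independent. It was 3.14 times (jackknife SE 0.0632) over 100 kb bins, which is the firmer value. These values argue against an even factor only. Unmethylated DNA or conversion that varied along the genome was not tested. A lower level of this clone itself, for instance through its culture history or growth state, may remain as an explanation and was not tested, and since Control 1 carries the Control label, how much of the gap belongs to the genotype stays open.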

How the results depend on the processing

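The CpG-poorer gene end, overlapping windows counted once and density-matched coverage were chosen after seeing the data; all other settings were planned. Direction held for the genome-wide difference in every setting run: 9.80 points with each CpG counted once, 10.7 at 10 or more calls, 10.8 after mitochondrial correction, and 2.64 to 18.9 with 1 library left out (the lone clone is then assumed to vary like the other pair). The values gave no sign that the replicate numbers pair the samples (correlation of same-number deviations 0.0462 over tiles and 0.127 over gene ends, only 2 pairs). A shift equal in all regions would not show in this correlation, so pairing is not excluded. With the number as a block the genome-wide difference was again 10.8, higher tiles numbered 7209, gene ends 44 higher and 1 lower, and 5 lists were called as before. Higher tiles, 2599 as reported, numbered 64323 without overdispersion, 19 at 1 or more calls, 4578 and 318 at minimum differences of 10 and 30 points, 27 with centred levels, 4349 and 772 for tiles of 500 bp and 2 kb, 4486 with thinned calls and 69 to 840581 with 1 library left out. Lower tiles, 0 as reported, numbered 78 without overdispersion, 2 at 10 points, 2 centred, 1 for 500 bp tiles and 0 to 113 with 1 library left out. Higher gene ends, 61 as reported, numbered 12 with edgeR, 9097 without overdispersion, 3 centred, 29 at the CpG-poorer end and 17 to 16103 with 1 library left out. Lower gene ends, 1 as reported, numbered 0 with edgeR, 3 without overdispersion, 0 centred, 0 at 20 points, 0 at the CpG-poorer end and 0 to 2 with 1 library left out. No list (0 of 5) was called with an estimated correlation, where all 12 lists shared an adjusted p of 0.863 (camera). Fisher's exact test on pooled CpG calls gave 760922 higher and 757 lower. With classes taken from Control 2 and the difference from the others, tiles at 80% or more differed by 18.98 points, since only Control 1 was then left as Control. Shares of calls over 10% off numbered 2 without tiles of high coverage and 4 when density-matched. Peg13 and Mest changed direction: their differences ranged from -0.341 to 71.2 and from -2.01 to 65.2 points with 1 library left out, and Gadd45a was at -5.21 points at the CpG-poorer end. Except for left-out libraries and settings that alter the threshold or overdispersion by construction, the cause was not tested. For the 18 named gene ends called as reported, 157 of 216 settings kept the call, 57 lost it and 2 changed direction, and Gadd45a and Gadd45g stayed uncalled in their 24 settings. These counts include settings that could hardly remove a call, such as no overdispersion or Control 2 left out. They also count overlapping gene ends, such as Plagl1 and Hymai, separately, so they are no measure of robustness. For the 5 lists called, 34 of 40 settings kept the call and 6 lost it, and for the 7 others 1 of 56 gained one. Tile class differences stayed above 0 in all 52 settings, but most of their size rests on Control 1. Depth was lowest at single CpGs, with a median of 23 to 28 calls against 141 to 195 per tile, so their levels are the least precise.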

Other observations

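The tests on imprinted gene ends and on chromosome 14 in this part were chosen only after the result was seen. Further imprinted loci outside the fixed naming rule, picked after their values were seen, carried runs of called tiles. Impact, a paternally expressed imprinted gene (chromosome 18, 12972001 to 12975000), was at 0.571% and 0.559% in Control and 41.8% and 40.3% in TKO over 3 tiles. The shared region of Peg10 and Sgce (chromosome 6, 4746001 to 4750000) was at 2.60% and 3.65% in Control and 38.9% and 45.3% in TKO, and Inpp5f (chromosome 7, 128687001 to 128691000), with an imprinted transcript, at 20.6% and 27.5% against 53.7% and 59.6%. All tiles of these 3 runs were also called without Control 1.

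Outside imprinted loci, runs of called tiles lay over Klf3, a Krüppel-like transcription factor (chromosome 5, 64815001 to 64823000, 37.3% and 59.3% in Control, 72.4% and 72.8% in TKO, 6 tiles), and Glo1, the glyoxalase gene (chromosome 17, 30603001 to 30608000, 25.5% and 45.6% in Control, 62.4% and 60.0% in TKO, 5 tiles), with 0 and 1 of their tiles called without Control 1. A run over Adprh (chromosome 16, 38447001 to 38451000, 23.3% and 31.1% in Control, 55.2% and 57.9% in TKO) kept all 3 of its tiles. The gene end of Ly6k, a GPI-anchored surface protein of the germline, was at 40.1% and 37.6% in Control and 70.9% and 68.1% in TKO and was called with and without Control 1 (limma adjusted p 0.000392 and 0.000225).

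Methylation was higher in TKO at 15 imprinted gene ends or 13 loci with overlapping ends joined, and both Control clones were under 10% at 6 of the loci. Control 1's low genome-wide level as the cause of the whole pattern is argued against, since at 9 loci, or 11 gene ends, both TKO clones lay at least 20 points above Control 2, against 26 such gene ends among all 32509. Peg13, H19, Mest and Meg3 differ from Control 2 by under 10 points, so their calls rest on Control 1. At Peg13, H19 and Mest, Control 1 was at 23.7%, 33.9% and 19.8% against 95.2%, 88.2% and 87.1% in Control 2. Over 1 kb tiles at 80% or more in Control 2, the 10th percentile of Control 1 was 63.6%. These values of 1 library argue against its genome-wide level alone as the cause at Peg13, H19 and Mest. For Meg3, at 12.7% and 37.2%, it stays open. Loss or gain of a copy in the TKO clones relative to Control 2 is argued against by coverage within 1 Mb of the genes, as 0 loci departed from Control 2 in either TKO clone by the margin set for it, with density-matched ratios of 0.953 to 1.03. The ratio of Control 1 to Control 2 ran from 0.946 at Plagl1 to 1.21 at H19. Coverage does not tell the parental copies apart, so an exchange of 1 for the other at an unchanged copy number was not tested. The genotype and differences between single clones that do not follow the genotype, known for imprints of cultured ES cells, cannot be told apart: of the 3 splits of the 4 libraries 1, the real one, called as many as 15, the highest other 6, and 3 splits are too few for a share under 0.05. Higher methylation at imprinted loci without GADD45 proteins may therefore be kept only as a hypothesis. Whether the TKO clones gained or the Control clones lost methylation was not tested, and the answer may differ between loci. Levels in TKO 1 and TKO 2 were 31.3% and 32.6% at Sgce and 40.4% and 40.6% at Peg3, with both Control clones under 10%. At Plagl1 they were 90.7% and 93.9% and at Nap1l5 92.7% and 94.6%, so the loci do not share 1 pattern.

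Low coverage of chromosome 14, common to all 4 libraries from 45.5 to 63 Mb, went on above 63 Mb in Control 2 and TKO 1. A tilt by CpG density is argued against, since the matched ratio was at most 0.504, and the genotype is argued against, since 1 Control clone had the low coverage and 1 TKO clone lacked it. Loss of 1 of 2 copies in these clones may explain it, with a lowest ratio of 0.496, though this was found and tested on the same data.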
